A study of Rattus norvegicus with 43 samples.

How the data were processed

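RNA of liver, lung and mammary gland of female rats was measured on Affymetrix rat genome arrays, 1 array per sample, 43 in all. The values are intensity values deposited by the authors as MAS5 signal per probe set, per the labels, on a linear scale. The 2% trimmed mean was between 1501.78 and 1503.29 on every array, so the authors had scaled the arrays globally and no further scaling was applied. The MAS5 version, the scanner and the detection calls are not given in the sources used here. Of 8799 probe sets, 59 controls were left out, which left 8740; 3 values in the table were 0. The number of arrays limits the precision. No genome was used, so no positions are given.

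Probe sets were named from the platform annotation: 7018 had 1 gene symbol, 308 had several genes and 1473 had none. Of those with 1 gene, 6994 had an Entrez ID found in the RefSeq table for rat, 0 symbols changed and 4737 distinct genes were covered. Groups were taken from the sample labels, as agent and organ.

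Signals were converted to log2 of the signal plus a pseudocount of 38.1, which is the 10th percentile of all values. A probe set was tested in an organ where its signal was above the 40th percentile of the array on at least 3 arrays, which gave 6084 in liver, 5935 in lung, 6059 in mammary gland and 5120 in all of them. Each organ was fitted apart with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend), with all 4 groups in the fit, and each agent was compared with diet and with each other agent. Whether the change against diet differed between organs was tested with a moderated F test in a fit of all 43 arrays. P-values were adjusted by Benjamini-Hochberg over the probe sets tested, and an adjusted p under 0.05 counts as passing. These choices, the gene lists and the rule for named genes were made before the data were examined.

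In all, 37 lists were fixed, 20 of pathways and 17 of cell type markers, and those with at least 5 measured genes were tested with camera at a preset correlation of 0.01, using 1 probe set per gene, and again with an estimated correlation. Passing members were also counted with p-values adjusted over the list alone. Named genes followed a rule. Against diet, the 10 largest rises and 10 largest falls were eligible among passing probe sets with 1 gene symbol and no overlap between the groups. From each list up to 4 passing members were eligible, or up to 2 given as not passing where fewer than 2 passed, together with 10 genes of retinoid handling wherever measured. Between agents the 5 largest differences each way were eligible, and for organ differences the 8 smallest p-values. Where fewer than 5 probe sets passed, the 5 smallest p-values were eligible as not passing, and in liver members of the lipid lists could be given for all agents. The text names a part of these, mostly genes that passed in every fit that left out 1 array. The values of 4 genes between agents, Fasn, Scd, Cyp2c22 and Cyp26b1, were given whether or not they passed, a choice made after their values were seen.

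The alternatives were quantile normalization, no filter on low values, a pseudocount 4 times larger, a block for arrays of the same number, array quality weights, a fit of only the 2 groups compared, and leaving out each array in turn. Arrays of the same number were checked for pairing: the median correlation of residuals between groups was -0.000861 in liver, 0.0256 in lung and 0.0124 in mammary gland, and the consensus correlation was 0.0732, so arrays were not paired. Leaving out the liver-dominant probe sets was added after the data were seen. In lung or mammary gland, these had a mean signal over all liver arrays, treated ones included, of at least 4 times the mean over all arrays of that organ. For the organ differences, a probe set counted if it met this in lung or in mammary gland. Genes that an agent raised in liver, such as Acot1 and Scd, can meet it without a high signal in untreated liver, so the counts were repeated with the same rule on the diet arrays alone. Also added after the data were seen was leaving out 4 arrays in doubt: diet liver 2, 4HPR liver 4, Targretin lung 2 and Targretin mammary gland 3. Liver-restricted probe sets, 190 in number, had a mean liver signal of at least 8000 and at least 20 times the median lung signal; 175 of them were liver-dominant on the diet arrays in both other organs.

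The procedure was tested on simulated data with 200 changed probe sets. For Targretin against diet, changes of 4-fold were recovered in 86.4% of cases in liver, 80.3% in lung and 78.8% in mammary gland, and changes of 2-fold in 44.8%, 32.8% and 32.8%. Changes of 1.5-fold were recovered in 14.9%, 1.49% and 1.49%. For the organ differences, 78.8% were recovered at 4-fold, 17.9% at 2-fold and 4.48% at 1.5-fold. The share of false calls was 7.62% in liver, 5% in lung, 0% in mammary gland and 4.29% for the organ differences. A comparison without changes gave 0 calls. The simulated noise was independent between probe sets, so these shares do not cover structure shared across an array, such as RNA quality or transcripts of another tissue. Overlap of calls between agents was set beside simulated unchanged groups and beside counts with the diet arrays split between agents. Overlap between organs was tested by the two-sided Fisher exact test. Other groupings of the arrays were counted for every comparison.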

Results

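Transcript levels were measured in liver, lung and mammary gland of female Sprague-Dawley rats, an outbred laboratory strain, after 7 days of treatment that began at 100 days of age. The agents were Targretin (bexarotene, a ligand of the retinoid X receptors), 9-cis retinoic acid (9cRA, a ligand of both the retinoic acid and the retinoid X receptors) and 4-hydroxyphenylretinamide (4HPR, a synthetic amide of retinoic acid). Targretin was given by gavage at 60 mg per kg body weight, 9cRA at 100 mg per kg diet and 4HPR at 782 mg per kg diet, so doses and routes differed. The untreated rats received diet only, and the labels name no gavage control. The 43 arrays formed 12 groups of 4 arrays each, except for 3 arrays in Targretin liver, Targretin lung, Targretin mammary gland, diet lung and 4HPR mammary gland. Median signal per array was 265.9 to 389.7 in liver, 466.2 to 633.3 in lung and 346.9 to 441.4 in mammary gland. The question was which transcripts each agent alters in each organ. The number of arrays limits the precision, and the p-values of limma measure only the spread between arrays, since the labels do not say that arrays of a group came from separate animals. Changes are log2 differences, agent minus diet, with standard errors from limma. Signals are means ± SD.

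In Targretin-treated livers, genes of fatty acid use and fatty acid synthesis rose together. The signal of Acot1, which hydrolyses long-chain acyl-CoA in the cytosol, was 39556.5 ± 9476 on 3 arrays against 75.7 ± 31.9 on 4 diet arrays, a rise of 8.46 ± 0.63 (adjusted p = 1.2e-07). Acaa1b, a peroxisomal thiolase, rose by 4.39 ± 0.31, from 1816 ± 301 to 39098 ± 7711. Pdk4, a kinase that restrains pyruvate oxidation, rose by 4.08 ± 0.60, and Cyp17a1, a steroid hydroxylase, rose by 4.10 ± 0.41. Slc41a2, a magnesium transporter, fell by 2.14 ± 0.17, from 9267 ± 1064 to 2068 ± 253.

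Of the 32 genes measured for fatty acid oxidation and PPARA targets, 18 rose with Targretin in liver, 0 fell and 14 did not pass, and 19 passed when adjusted over the list alone. Ehhadh, the peroxisomal bifunctional enzyme, rose by 2.72 ± 0.24, Plin2, a lipid droplet coat protein, by 2.41 ± 0.23, Pex11a, a peroxisome division factor, by 2.50 ± 0.33, and Cyp4a1, a fatty acid hydroxylase, by 1.65 ± 0.19. The mean of the list was 1.31 (camera adjusted p = 4.8e-16, and adjusted p = 0.0081 with an estimated correlation). Of 14 lipogenesis and LXR target genes, 9 rose and 5 did not pass, with 11 adjusted over the list alone and a mean of 1.60 (camera adjusted p = 2.0e-10, and adjusted p = 0.013 with an estimated correlation). Fatty acid synthase, Fasn, rose by 3.03 ± 0.19 (adjusted p = 1.9e-08), the desaturases Scd and Scd2 by 2.84 ± 0.30 and 2.91 ± 0.39, and Pnpla3, a lipid droplet acyltransferase and hydrolase, by 3.46 ± 0.48. Malic enzyme, Me1, rose by 1.91 ± 0.25. Igfbp2, a binding protein of insulin-like growth factors, rose by 3.33 ± 0.25, while Igfbp3 fell by 1.39 ± 0.20.

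Other groups in Targretin liver moved down or in both directions. Of 19 heat shock and unfolded protein genes, 5 fell, 0 rose and 14 did not pass, with 7 adjusted over the list alone and a mean of -0.43 (camera adjusted p = 0.0019, and adjusted p = 0.026 with an estimated correlation). The chaperone Hsph1 fell by 1.17 ± 0.15. Of 8 circadian clock genes, 4 fell, 0 rose and 4 did not pass, with 4 adjusted over the list alone and a mean of -1.02 (camera adjusted p = 0.0010, and adjusted p = 0.045 with an estimated correlation). Bhlhe41 fell by 2.34 ± 0.43, Per2 by 2.09 ± 0.43 and Dbp by 1.84 ± 0.31. Of 14 macrophage and antigen presenting cell markers, 5 fell and 9 did not pass, with 6 adjusted over the list alone and a mean of -0.57 (camera adjusted p = 0.0017, but adjusted p = 0.49 with an estimated correlation). The invariant chain of class II molecules, Cd74, fell by 1.51 ± 0.23. Among 30 drug metabolism genes, 4 rose, 3 fell and 23 did not pass, with 8 adjusted over the list alone (camera adjusted p = 0.99). Cyp2b2 rose by 2.91 ± 0.20 and Cyp2b15 by 0.96 ± 0.16, while Cyp3a18 fell by 1.92 ± 0.22 and Cyp1a2 by 1.23 ± 0.16. Among 11 retinoid handling genes, 3 rose, 2 fell and 6 did not pass, with 5 adjusted over the list alone (camera adjusted p = 0.48). Cyp26b1, which clears retinoic acid, rose by 2.34 ± 0.45 (538 ± 220 against 78.1 ± 47.0), Aldh1a1, a retinaldehyde dehydrogenase, rose by 0.98 ± 0.22, and Rdh7, a retinol dehydrogenase, fell by 1.15 ± 0.18. The retinoic acid receptor gene Rarb differed by 0.89 ± 0.59 (adjusted p = 0.40).

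Of 20 glucose metabolism genes, 7 rose, 2 fell and 11 did not pass, with 10 adjusted over the list alone and a mean of 0.46 (camera adjusted p = 0.029, but adjusted p = 0.23 with an estimated correlation). Pdk2, a kinase related to Pdk4, rose by 1.38 ± 0.14, and the glucose transporter gene Slc2a2 fell by 0.67 ± 0.15. This list lost its call without Targretin array 1, Targretin array 3 or diet array 2 (adjusted p = 0.051, 0.070 and 0.054).

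By limma, 678 of the 6084 probe sets tested in liver passed at an adjusted p under 0.05 for Targretin, 297 higher and 381 lower, in 451 genes. The count was 420 without Targretin array 2.

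**Figure D1:**
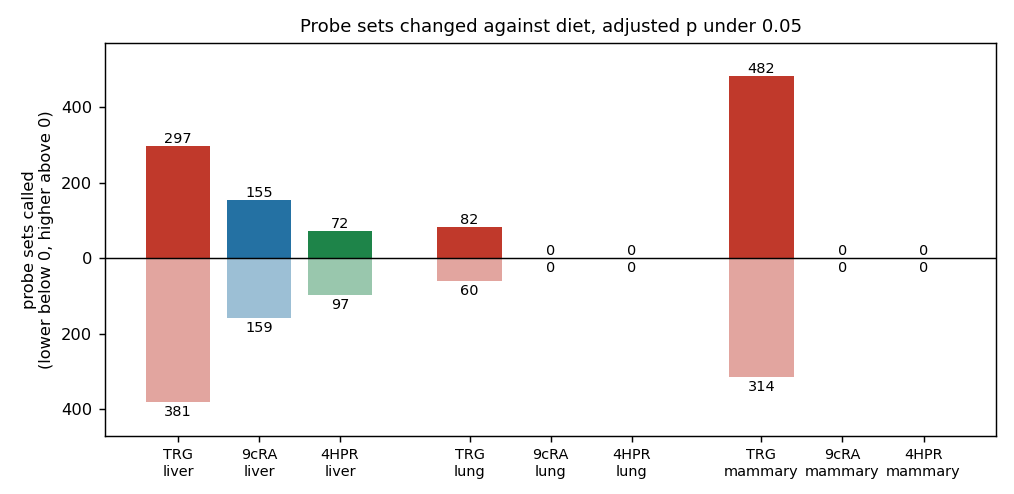
Probe sets called against diet (y axis, count) for each agent in liver, lung and mammary gland, with bars for higher and lower calls. Targretin gave 678 calls in liver, 142 in lung and 796 in mammary gland, while 9cRA and 4HPR gave 314 and 169 in liver and 0 in lung and in mammary gland.

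In livers of rats fed 9cRA, the rise with the smallest p was that of Cyp2c22, a cytochrome P450 of liver, by 2.26 ± 0.11 (56145 ± 3094 against 11737 ± 1261 in diet livers, n = 4 each, limma adjusted p = 1.5e-09). Igfbp2 rose by 1.82 ± 0.23, from 906 ± 377 to 3100 ± 271. Hao2, a peroxisomal hydroxy acid oxidase, fell by 1.92 ± 0.24, from 1197 ± 447 to 280 ± 60.6. The amino acid degrading enzymes Sds and Tat fell by 1.82 ± 0.34 and 1.46 ± 0.27, and the clock gene Per2 fell by 2.06 ± 0.40. Cox5b, a subunit of cytochrome oxidase, rose by 1.89 ± 0.23, and the cytosolic isocitrate dehydrogenase Idh1 by 1.98 ± 0.31.

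Of the 32 fatty acid oxidation genes, 2 rose with 9cRA and 30 did not pass, with 4 adjusted over the list alone (camera adjusted p = 0.72). Of 14 lipogenesis genes, 3 rose, 1 fell and 10 did not pass, with 5 adjusted over the list alone (camera adjusted p = 0.47); the list mean was 0.16 while its median was -0.08. Scd rose by 1.82 ± 0.27 on 1 of its 2 probe sets and Fasn by 1.0 ± 0.17, while Scd2 fell by 1.81 ± 0.36. Of 19 acute phase genes, 7 rose and 12 did not pass, with 11 adjusted over the list alone and a mean of 0.40. Orm1, a plasma glycoprotein, rose by 1.15 ± 0.14 and ceruloplasmin, Cp, by 0.62 ± 0.12. This list passed camera (adjusted p = 4.6e-07) but gave adjusted p = 0.65 with an estimated correlation and adjusted p = 0.089 after quantile normalization. Beside it, of 15 hepatocyte markers 4 rose, 2 fell and 9 did not pass, with 12 adjusted over the list alone and a mean of 0.15 (camera adjusted p = 0.042, but adjusted p = 0.69 with an estimated correlation). That mean turned to -0.20 after quantile normalization (adjusted p = 0.21). Among 19 heat shock and unfolded protein genes, 1 fell and 18 did not pass, with 2 adjusted over the list alone and a mean of -0.41 (camera adjusted p = 0.0021, and adjusted p = 0.064 with an estimated correlation). That member, Hsph1, fell by 1.01 ± 0.14. Of 30 drug metabolism genes, 3 rose, 6 fell and 21 did not pass, with 13 adjusted over the list alone (camera adjusted p = 0.61). Cyp3a9 rose by 0.89 ± 0.17, and Gstm1, Cyp3a18 and the canalicular transporter gene Abcc2 fell by 0.88 ± 0.15, 1.04 ± 0.21 and 0.95 ± 0.20. Of the retinoid genes, Cyp26b1 differed by 0.90 ± 0.41 (adjusted p = 0.24), Aldh1a1 by -0.46 ± 0.20 (adjusted p = 0.21) and Rarb by -0.10 ± 0.55 (adjusted p = 0.95), with the sign of Rarb turned without 9cRA array 1 (0.27), 9cRA array 4 (0.19) or diet array 1 (0.0445). Cholesterol synthesis genes passed camera with a mean of 0.39, where 1 of 15 rose and 14 did not pass, with 4 adjusted over the list alone (adjusted p = 0.0017, but 0.68 with an estimated correlation and 0.051 without diet array 2). Macrophage markers, with 2 of 14 lower, 12 not passing and 5 adjusted over the list alone, had a mean of -0.37 (camera adjusted p = 0.032, but adjusted p = 0.68 with an estimated correlation). Their call was lost without 9cRA array 1, 2 or 3 or diet array 1 (adjusted p = 0.065, 0.13, 0.090 and 0.085) and after quantile normalization (adjusted p = 0.064). Cd74 fell by 0.96 ± 0.21.

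By limma, 314 probe sets in liver passed for 9cRA, 155 higher and 159 lower, in 232 genes. The count was 203 without diet array 1, 207 without diet array 3 and 483 with array quality weights.

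In livers of rats fed 4HPR, Cyp2c22 rose by 2.19 ± 0.11 to 53752 ± 4998 (n = 4, limma adjusted p = 2.4e-09). Cyp26b1 rose by 2.49 ± 0.41, from 78.1 ± 47.0 to 585 ± 155. Scd rose on 1 of its 2 probe sets by 1.76 ± 0.27, from 10098 ± 4438 to 33143 ± 10113, and Fasn by 1.08 ± 0.17. Hao2 fell by 2.14 ± 0.24 to 236 ± 57.4, and Scd2 fell by 1.76 ± 0.36. The sulphinic acid decarboxylase of taurine synthesis, Csad, rose by 1.68 ± 0.26, and the cortisone reductase Hsd11b1 by 1.42 ± 0.29.

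Among the 32 fatty acid oxidation genes, 1 rose with 4HPR, 2 fell and 29 did not pass, with 5 adjusted over the list alone (camera adjusted p = 0.39). The members that fell were those of mitochondrial beta-oxidation, Acadm by 0.64 ± 0.12 and Hadhb by 0.65 ± 0.13. The member that rose, Acot1 by 2.34 ± 0.58, lost its call without any single diet array and without 4HPR array 3 or 4 (adjusted p up to 0.103). Among 14 lipogenesis genes, 2 rose, 1 fell and 11 did not pass, with 4 adjusted over the list alone (camera adjusted p = 0.17). Of 15 cholesterol synthesis genes, 1 rose and 14 did not pass, with 5 adjusted over the list alone and a mean of 0.52 (camera adjusted p = 3.6e-08, but adjusted p = 0.44 with an estimated correlation). The member that rose was Cyp51, a sterol demethylase, whose call was lost without 4HPR array 1, 4HPR array 3 or diet array 2 (adjusted p up to 0.0810). Of 30 drug metabolism genes, 3 rose and 27 did not pass, with 7 adjusted over the list alone and a mean of 0.18. Cyp3a9 rose by 1.10 ± 0.17 and Cyp3a23-3a1 by 1.04 ± 0.20. The list gave a camera adjusted p of 5.2e-04, adjusted p = 0.16 with an estimated correlation and adjusted p = 0.25 after quantile normalization. Among 19 acute phase genes, 2 rose and 17 did not pass, with 2 adjusted over the list alone and a mean of 0.22. Orm1 rose by 0.90 ± 0.14 and Cp by 0.69 ± 0.12. This list gave a camera adjusted p of 1.2e-04, adjusted p = 0.52 with an estimated correlation and adjusted p = 0.89 after quantile normalization. Quantile normalization moved the median of all probe sets in this comparison from -0.10 to -0.0043. Of 14 macrophage markers, 4 fell and 10 did not pass, with 6 adjusted over the list alone (camera adjusted p = 0.19), among them Cd74 by 1.14 ± 0.21. Rarb differed by 0.43 ± 0.55 (adjusted p = 0.72) and Aldh1a1 by -0.10 ± 0.20 (adjusted p = 0.84; 0.0349 without 4HPR array 1).

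By limma, 169 probe sets in liver passed for 4HPR, 72 higher and 97 lower, in 126 genes. The count was 103 without 4HPR array 1, 280 without 4HPR array 4, 92, 100 and 106 without diet arrays 2, 3 and 4, and 443 with array quality weights.

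**Figure D2:**
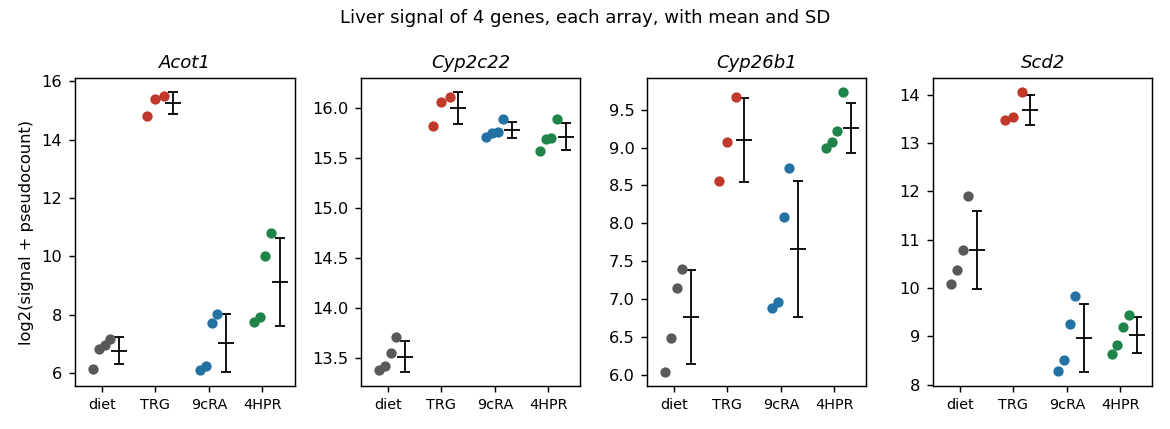
Signal in liver of Acot1, Cyp2c22, Cyp26b1 and Scd2 (y axis, log2 of signal plus the pseudocount) on each array of the 4 groups, with points for arrays and bars for the mean and SD. The change in Cyp2c22 was 2.48 with Targretin, 2.26 with 9cRA and 2.19 with 4HPR, whereas Scd2 changed by 2.91, -1.81 and -1.76.

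The agents, related retinoids given at unlike doses and routes, were compared directly in liver. Cyp2c22 rose by 2.48 ± 0.12 with Targretin, and its level did not pass the test between any pair of agents: Targretin minus 9cRA was 0.22 (95% interval -0.03 to 0.47, adjusted p = 0.412), Targretin minus 4HPR was 0.28 (0.03 to 0.54, adjusted p = 0.169) and 9cRA minus 4HPR was 0.07 (-0.17 to 0.30, adjusted p = 0.841). Fasn was higher with Targretin than with 9cRA by 2.03 (1.64 to 2.43, adjusted p = 1.6e-06) and than with 4HPR by 1.95 (1.56 to 2.35, adjusted p = 2.9e-06), and 9cRA minus 4HPR was -0.08 (-0.45 to 0.28, adjusted p = 0.873), or 0.00404 without 4HPR array 4. Scd2 separated the agents by direction, since it was higher with Targretin than with 9cRA by 4.72 ± 0.39 and than with 4HPR by 4.66 ± 0.39. For Scd, Targretin minus 9cRA was 1.02 (0.40 to 1.64, adjusted p = 0.0519), Targretin minus 4HPR was 1.08 (0.46 to 1.71, adjusted p = 0.0316) and 9cRA minus 4HPR was 0.06 (-0.52 to 0.64, adjusted p = 0.945). The second lost its call without any 1 of the Targretin arrays or 4HPR arrays 1 and 3 (adjusted p up to 0.0916), and the third turned negative in some fits, such as -0.0929 without 9cRA array 4. Cyp26b1 did not pass between Targretin and 4HPR, at -0.15 (-1.10 to 0.79, adjusted p = 0.877), nor between 9cRA and 4HPR, at -1.59 (-2.47 to -0.72, adjusted p = 0.157), nor between Targretin and 9cRA, at 1.44 (0.49 to 2.38, adjusted p = 0.0752). The value of Cyp26b1 for Targretin minus 4HPR turned positive without 4HPR array 1 (0.00373) or Targretin array 3 (0.115).

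Fatty acid oxidation and lipogenesis genes were higher with Targretin than with either other agent. Against 9cRA, 17 of 32 fatty acid oxidation genes were higher, 0 were lower and 15 did not pass, with 19 adjusted over the list alone and a mean difference of 1.24 (camera adjusted p = 6.5e-19, and adjusted p = 0.0041 with an estimated correlation). Against 4HPR, 20 were higher, 0 were lower and 12 did not pass, with 22 adjusted over the list alone and a mean of 1.48 (camera adjusted p = 4.3e-20, and adjusted p = 0.0031 with an estimated correlation). Ehhadh differed by 2.51 ± 0.24 and 2.46 ± 0.24 in those comparisons and Acot1 by 8.21 ± 0.63 and 6.12 ± 0.63. Of 14 lipogenesis genes, 8 were higher than with 9cRA and 8 than with 4HPR, 6 did not pass in each, 10 passed in each adjusted over the list alone, and the means were 1.45 and 1.48 (camera adjusted p = 3.6e-11 and 3.2e-08, and adjusted p = 0.0098 and 0.031 with an estimated correlation). Other lipid lists were not higher. Of 15 cholesterol synthesis genes, 1 was higher and 3 were lower than with 9cRA and 11 did not pass, with a mean of -0.11 (camera adjusted p = 0.56), and 1 was lower and 14 did not pass against 4HPR, with a mean of -0.24 (camera adjusted p = 0.046, but adjusted p = 0.64 with an estimated correlation and 0.23 after quantile normalization). Cyp2b2 was higher with Targretin by 2.93 ± 0.20 and 2.86 ± 0.20, and Aldh1a1 by 1.44 ± 0.22 and 1.08 ± 0.22. The flavin monooxygenase Fmo1 was lower with Targretin than with 9cRA by -2.19 ± 0.20 and than with 4HPR by -2.87 ± 0.20. Clock genes were lower by a mean of -0.61 and -0.73, with 1 of 8 lower and 7 not passing in each comparison and 4 and 5 adjusted over the list alone (camera adjusted p = 0.0027 and 7.8e-04, but adjusted p = 0.081 and 0.055 with an estimated correlation). Between 9cRA and 4HPR, drug metabolism genes were lower with 9cRA by a mean of -0.29, with 1 of 30 lower, 29 not passing and 8 adjusted over the list alone (camera adjusted p = 4.9e-08, and adjusted p = 0.0094 with an estimated correlation). That member was the epoxide hydrolase Ephx1, lower with 9cRA by -1.17 ± 0.18 (adjusted p = 0.012, and 0.0517 without 9cRA array 2). Pex14, a peroxisomal import factor, was lower with 9cRA by -2.48 ± 0.34 (455 ± 167 against 2635 ± 439).

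By limma, 348 probe sets differed between Targretin and 9cRA in liver, 174 each way. Between Targretin and 4HPR the count was 479, 253 higher and 226 lower, and it was 318 without Targretin array 1, 280 without Targretin array 2 and 292 in a fit of only the 2 groups compared. Between 9cRA and 4HPR it was 10, 1 higher and 9 lower, with 0 higher and 7 lower after quantile normalization. That last count was 4 without 4HPR array 3, 3 without 9cRA array 2, 18 without 9cRA array 4, 22 with array quality weights and 6 in a fit of only the 2 groups. The agents shared calls in liver: 68 probe sets were higher and 80 lower with both Targretin and 9cRA, where independent calls would give 7.57 and 9.96. Targretin and 4HPR shared 36 higher and 53 lower (independent 3.51 and 6.07), and 9cRA and 4HPR shared 44 higher and 46 lower (independent 1.83 and 2.54). Opposite calls numbered 4, 9 and 1. Since the comparisons share their diet arrays, the overlap was also counted with the diet arrays split between the agents, which left 17 to 20 higher and 20 to 27 lower for Targretin and 9cRA, 1 to 14 and 2 to 16 for Targretin and 4HPR, and 4 to 16 and 2 to 6 for 9cRA and 4HPR. Independent calls in those fits would give at most 2.28, 1.81, 1.39, 1.26, 0.431 and 0.280 in the same order. Simulated unchanged groups that shared their diet arrays gave 0 shared calls. Unchanged groups give hardly any calls at all, so this count cannot show what shared diet arrays add to the overlap. The correlation of the changes across probe sets, which are not independent replicates, was 0.517, 0.404 and 0.622 for the pairs of agents and lay under the highest simulated values of 0.744, 0.789 and 0.724. The covariance of the changes was 0.149, 0.110 and 0.123 and lay above the highest simulated values of 0.0895, 0.0963 and 0.0999. With the diet arrays split, the correlation was 0.303 to 0.343, 0.157 to 0.263 and 0.271 to 0.388.

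**Figure D3:**
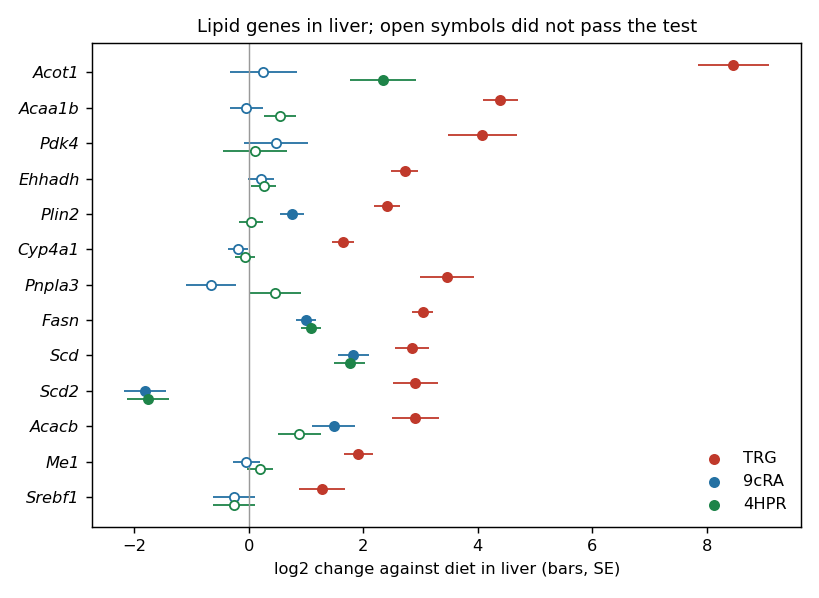
Change against diet in liver (x axis, log2, with bars for the standard error) of 13 lipid genes (y axis) with Targretin, 9cRA and 4HPR; open symbols did not pass. Acot1 differed by 8.46 with Targretin and 2.34 with 4HPR, and Scd2 was the gene that rose with Targretin and fell with both other agents.

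In lung, Targretin was followed by higher Cyp26b1, at 6440 ± 778 against 1338 ± 1682 in diet lungs (n = 3 each), a rise of 2.98 ± 0.62 (limma adjusted p = 0.031). The diet lungs were unlike each other for this gene, at 3280 on array 2 and 406 and 329 on the others. Targretin lung array 2 stood apart in RNA quality, with a log2 ratio of 3' to 5' signal of 1.34 for GAPDH and 2.45 for actin, where the other Targretin lungs had -0.16 and -0.02 for GAPDH and 0.42 and 0.56 for actin. Srebf1, a transcription factor of lipogenesis, rose by 2.29 ± 0.41, and the neutrophil calcium-binding proteins S100a8 and S100a9 rose by 1.51 ± 0.23 and 1.5 ± 0.24. Cdkn1b, an inhibitor of cyclin-dependent kinases, rose by 3.39 ± 0.68 to 632 ± 189. Lamp2, a lysosomal membrane protein, fell by 1.54 ± 0.27, Atp1b1, a subunit of the sodium pump, by 1.25 ± 0.23 and the clock gene Bhlhe41 by 1.28 ± 0.24. The retinoic acid receptor gene Rara rose by 0.84 ± 0.20, and Aldh1a1 differed by -0.27 (adjusted p = 0.51).

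No list of the 35 tested in lung passed camera for Targretin, and the smallest adjusted p was 0.11. Among 20 apoptosis and growth arrest genes 2 rose, 18 did not pass and 9 passed when adjusted over the list alone. Hepatocyte markers, 14 genes, had a mean of -0.73, with 0 passing and 1 adjusted over the list alone (camera adjusted p = 0.11). By limma, 142 of 5935 probe sets passed, 82 higher and 60 lower, in 119 genes, and after quantile normalization the split was 52 higher and 71 lower. The count rested on single arrays: it was 20 without Targretin array 1, 460 without Targretin array 3, 299 without diet array 2, 1 without diet array 3 and 0 without diet array 4, so each lung gene named for Targretin lost its call in that last fit. It was 0 in a fit of only the 2 groups compared, 697 with array quality weights, and 155 without Targretin array 2.

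With 9cRA or 4HPR, no probe set in lung passed the test, though many did with array quality weights (964 and 398), and 1 did for 9cRA both without a filter and in a fit of only the 2 groups. The smallest p for 9cRA included that of Scd, which differed by -1.51 ± 0.29 (3108 ± 863 against 8714 ± 1195, adjusted p = 0.31), and Cyp26b1 differed by -0.30 ± 0.58 (adjusted p = 0.87), or by 0.71 without diet array 2. With 4HPR the Cyp26b1 signal was 5101 ± 1849 against 1338 ± 1682, a difference of 2.58 ± 0.58 (adjusted p = 0.55). The 4HPR lungs had 3075 to 6683, above diet arrays 3 and 4 at 406 and 329, while diet array 2 had 3280. Liver transcripts such as Apoc3, an apolipoprotein, and Cyp2c12, a cytochrome P450 of female liver, differed by 3.83 ± 0.98 and 3.46 ± 0.84 with 4HPR (adjusted p = 0.55). All 14 hepatocyte markers failed over all genes, 11 passed when adjusted over the list alone, and their mean was 1.87 with 4HPR (camera adjusted p = 2.6e-16, but adjusted p = 0.20 with an estimated correlation). Acute phase genes had a mean of 1.22 over 19 genes, with 0 passing and 9 adjusted over the list alone (camera adjusted p = 1.1e-11, but adjusted p = 0.20 with an estimated correlation). With 4HPR, 9 lists passed camera in lung and 0 of them with an estimated correlation. With 9cRA, 6 passed, with adjusted p between 0.040 and 0.047, and 0 with an estimated correlation; among them were 16 cell division genes with a mean of 0.42, a call lost without 9cRA array 2 or 3 or diet array 2 or 3 (adjusted p = 0.19, 0.13, 0.053 and 0.057). Liver-restricted probe sets in lung stood at 1.35 to 9.91% of their liver signal on 9cRA and 4HPR arrays, 0.730 to 0.986% on Targretin arrays, and 3.5, 0.494 and 0.609% on diet arrays 2, 3 and 4.

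By limma the counts in lung were 0 for 9cRA and 0 for 4HPR, with 656 and 273 probe sets at an unadjusted p under 0.05 where chance would give 296.75. Without diet array 2 the counts were 38 for 9cRA, 29 higher and 9 lower, and 80 for 4HPR, 77 higher and 3 lower.

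Between agents in lung, Scd was higher with Targretin than with 9cRA by 2.20 ± 0.29 (14470 ± 4163 against 3108 ± 863, adjusted p = 0.012), which lost its call without Targretin array 1, 9cRA array 3 or 9cRA array 4 (adjusted p up to 0.125). Cyp26b1 did not pass between Targretin and 9cRA, at 3.28 (95% interval 2.04 to 4.52, adjusted p = 0.0977), between Targretin and 4HPR, at 0.40 (-0.84 to 1.64, adjusted p = 0.702), or between 9cRA and 4HPR, at -2.88 (-4.03 to -1.73, adjusted p = 0.127). Liver transcripts were lower with Targretin than with 4HPR, among them Cyp2c7 by -6.56 ± 1.25, albumin, Alb, by -6.14 ± 1.17 and Cyp2c6v1 by -5.14 ± 0.83. Of 14 hepatocyte markers, 7 were lower and 7 did not pass, with 11 adjusted over the list alone and a mean of -2.60 (camera adjusted p = 2.1e-11, but adjusted p = 0.73 with an estimated correlation).

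Targretin against 9cRA in lung gave 1 call, higher, and after quantile normalization 1 higher and 1 lower; the count was 5 without Targretin array 3 and 19 in a fit of only the 2 groups. Targretin against 4HPR gave 86, 38 higher and 48 lower, all named genes of which lost their call in some fit: the count was 0 without 4HPR array 2, 4HPR array 3 or Targretin array 1, 1 without 4HPR array 4, 352 without Targretin array 3, 44 with array quality weights and 39 in a fit of only the 2 groups. Without the liver-dominant probe sets, left out after the data were seen, these counts were 0 and 1, or 1 and 1 with liver dominance judged on the diet arrays alone. For 9cRA against 4HPR limma gave 0 calls, with 566 at an unadjusted p under 0.05 where chance would give 296.75.

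In mammary gland, transcripts of liver proteins were far lower on the Targretin arrays than on the diet arrays. Transthyretin, Ttr, a plasma carrier made by liver, fell by 7.02 ± 0.45, from 13611 ± 1833 on 4 arrays to 83.9 ± 86.3 on 3 (limma adjusted p = 1.3e-07). The liver sulphotransferase Sult2a1 fell by 6.24 ± 0.38, Cyp2c12 by 6.28 ± 0.39, Ahsg, a plasma glycoprotein, by 6.71 ± 0.52, and Fabp1, the fatty acid binding protein of liver, fell by 6.20 ± 0.44. Of 15 hepatocyte markers, 15 fell, and 15 passed when adjusted over the list alone, with a mean of -3.83 (camera adjusted p = 5.5e-21, but adjusted p = 0.15 with an estimated correlation). Liver-restricted probe sets stood at 0.640 to 0.732% of their liver signal on Targretin mammary arrays and at 2.48 to 7.42% on the other mammary arrays.

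Lists that hold liver genes moved with them. Among 19 acute phase genes 12 fell and 7 did not pass, with 15 adjusted over the list alone and a mean of -1.86 (camera adjusted p = 9.9e-08, but adjusted p = 0.18 with an estimated correlation). Fibrinogen chains Fga and Fgb fell by 4.42 ± 0.45 and 3.84 ± 0.46. Among 29 drug metabolism genes 12 fell, 2 rose and 15 did not pass, with 17 adjusted over the list alone and a mean of -1.24 (camera adjusted p = 1.8e-07, but adjusted p = 0.24 with an estimated correlation). Of 14 apolipoprotein genes, 7 fell, 1 rose and 6 did not pass, with 9 adjusted over the list alone and a mean of -1.69 (camera adjusted p = 3.7e-07, but adjusted p = 0.28 with an estimated correlation). Apoc1 fell by 4.30 ± 0.36 and Apob by 2.75 ± 0.27.

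Other transcripts rose in mammary gland with Targretin against diet. With the liver-dominant probe sets left out, 551 probe sets passed against diet, but 0 against 9cRA and 0 against 4HPR. With all probe sets, 9 were higher than with 9cRA and 93 than with 4HPR. The changes against diet given here are thus not shown to be particular to Targretin. Aldoc, the brain-type aldolase, rose by 3.25 ± 0.65 (2785 ± 1620 against 253 ± 141), Psap, the precursor of lysosomal saposins, by 2.46 ± 0.51 (8267 ± 846 against 1516 ± 447) and the immediate early gene Fos by 2.42 ± 0.45 (770 ± 397 against 103 ± 44.4). The other probe set of Aldoc and 2 others of Fos did not pass, while 1 of 2 others of Psap rose. The receptor kinase Kit rose by 1.86 ± 0.39 and the epithelial mucin Muc1 by 1.03 ± 0.22. Catalase, Cat, fell by 1.09 ± 0.21 and Klf9, a thyroid and glucocorticoid responsive factor, by 1.09 ± 0.24. Of 13 retinoid handling genes, 1 rose, 1 fell and 11 did not pass, with 5 adjusted over the list alone (camera adjusted p = 0.54). The member that rose, Crabp2, a cellular retinoic acid binding protein, rose by 1.73 ± 0.46 (adjusted p = 0.024), a call lost without Targretin array 3, diet array 2 or diet array 3 (adjusted p up to 0.108). Cyp26b1 differed by 1.63 ± 0.73 (adjusted p = 0.15) and Aldh1a1 by -0.61 ± 0.21 (adjusted p = 0.062).

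By limma, 796 of 6059 probe sets in mammary gland passed for Targretin, 482 higher and 314 lower, in 594 genes, and with the liver-dominant probe sets left out, 405 higher and 146 lower, or 361 and 147 with dominance judged on the diet arrays alone. Quantile normalization moved the median of all probe sets from 0.11 to 0.0104. The log2 ratio of 3' to 5' signal was high on every mammary array, at 1.29 to 2.04 for GAPDH and 1.51 to 2.63 for actin. On the arrays of doubtful RNA quality, 4HPR liver 4 and Targretin lung 2, it was 1.18 and 1.34 for GAPDH and 1.57 and 2.45 for actin. How this bears on the mammary counts and on the differences between organs was not tested. The count was 514, 338 and 409 without Targretin arrays 1, 2 and 3, 375 and 368 without diet arrays 2 and 3, and 1308 with array quality weights. Targretin array 3 held skeletal muscle transcripts, with a mean log2 marker level of 10.50 against 7.47 to 7.95 on the other mammary arrays; without it, 216 were higher and 193 lower.

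**Figure D4:**
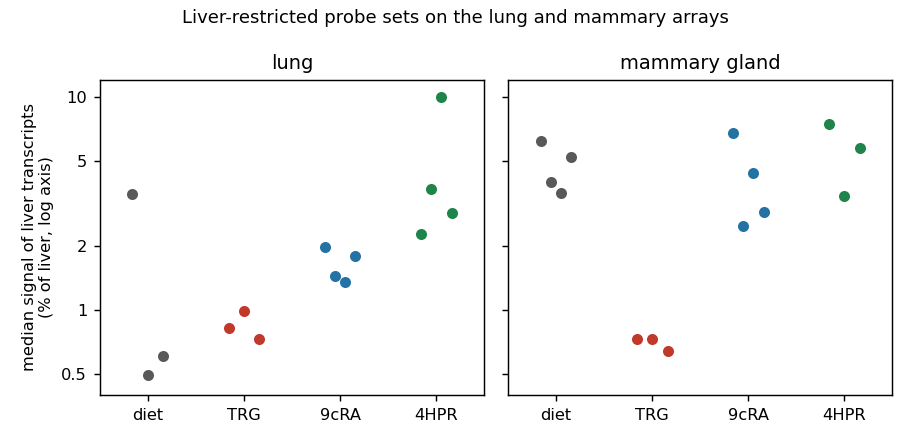
Median signal of 190 liver-restricted probe sets, as percent of their liver signal (y axis, log scale), on each lung and mammary gland array (points) of the diet, Targretin, 9cRA and 4HPR groups. Targretin mammary arrays lie between 0.640 and 0.732% and all 11 other mammary arrays between 2.48 and 7.42%.

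Neither 9cRA nor 4HPR gave a passing probe set in mammary gland. The diet arrays were unlike each other for Cyp26b1, at 561.5 and 568.7 on arrays 1 and 4 and 59.4 and 34.9 on arrays 2 and 3. The 4HPR arrays had 337.6 to 727. Acot1 parted the diet arrays likewise, at 1884.5 and 1400.9 on arrays 1 and 4 and 418.4 and 272.1 on arrays 2 and 3. The 4HPR arrays had 1402.6 to 1655.4. By Spearman correlation, diet arrays 1, 3 and 4 each matched a 4HPR array best (0.952, 0.948 and 0.945). Their highest values within the diet group were 0.936, 0.940 and 0.936, and diet array 2 matched diet array 3 best. The cause of this spread, a wrong label included, was not tested, and an effect of these agents could be hidden by it. For 9cRA the smallest p values were those of Afdn, a junction protein, at 1.39 ± 0.27, Chordc1, a chaperone partner, at -1.14 ± 0.23, and Ung, a uracil glycosylase, at 1.92 ± 0.39 (limma adjusted p = 0.13). For 4HPR they included Fgf16, a growth factor, at 1.44, and Jup, a junction protein, at 0.93 (adjusted p = 0.999). Crabp2 differed by 0.54 with 9cRA (adjusted p = 0.52). Of 9 myoepithelial and smooth muscle markers, 0 passed with 4HPR with 0 adjusted over the list alone, while the list mean was 0.41 (camera adjusted p = 0.0028, but adjusted p = 0.93 with an estimated correlation). The counts from limma were 0 for each, with 1130 probe sets for 9cRA and 180 for 4HPR at an unadjusted p under 0.05 where chance would give 302.95. For 9cRA the count was 147 without diet array 1, 83 higher and 64 lower, 1 without 9cRA array 3 and 2 without 9cRA array 4.

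Between agents in mammary gland, liver transcripts again parted Targretin from the others. Ttr was lower with Targretin than with 9cRA by -5.82 ± 0.45 and than with 4HPR by -6.78 ± 0.49, and Cyp2c12 by -5.70 ± 0.39 and -6.84 ± 0.42. Of 15 hepatocyte markers, 11 were lower than with 9cRA and 4 did not pass, with 15 adjusted over the list alone and a mean of -3.27 (camera adjusted p = 2.9e-34, and adjusted p = 0.019 with an estimated correlation). Against 4HPR 13 were lower and 2 did not pass, with 15 adjusted over the list alone and a mean of -3.87 (camera adjusted p = 1.8e-25, but adjusted p = 0.071 with an estimated correlation). Crp, the C-reactive protein of liver, was higher with 9cRA than with 4HPR by 1.99 ± 0.28 (4296 ± 776 against 1057 ± 236, adjusted p = 0.010), a call lost without 4HPR array 2 or 4HPR array 3 (adjusted p up to 0.133).

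Targretin against 9cRA gave 124 calls in mammary gland, 9 higher and 115 lower, and against 4HPR 256, 93 higher and 163 lower; with the liver-dominant probe sets left out, both counts were 0, however dominance was judged. For the second comparison, quantile normalization moved the median of all probe sets from 0.14 to 0.031, and the count was 140, 157 and 117 without 4HPR arrays 2, 3 and 4, 147 and 159 without Targretin arrays 2 and 3, 1108 with array quality weights and 458 in a fit of only the 2 groups. For 9cRA against 4HPR it was 3, all higher, and 1 without 4HPR array 2, 0 without 4HPR array 3, 6 without 9cRA array 2, 37 with array quality weights and 12 in a fit of only the 2 groups.

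The change with Targretin differed between organs for genes of several functions. Acot1 differed from diet by 8.46 in liver, 2.77 in lung and -1.34 in mammary gland (F test of limma, adjusted p = 2.1e-08), and Acaa1b by 4.39, 0.12 and -1.51 (adjusted p = 2.0e-07). On diet arrays, Acot1 had a mean signal of 75.7 in liver and 994 in mammary gland, and Acaa1b had 1820 and 703. Atp1b1 differed from diet by 1.46, -1.25 and -0.57 (adjusted p = 3.9e-07) and Dact2, a regulator of Wnt signalling, by 3.29, -0.06 and 0.63 (adjusted p = 7.9e-07). With 9cRA, Scd differed from diet by 1.82 in liver, -1.51 in lung and -0.37 in mammary gland (adjusted p = 8.1e-04), and Cd74 by -0.96, 0.39 and 0.83 (adjusted p = 0.014, but 0.0512 without liver 9cRA array 2 and 0.0524 without liver diet array 3). With 4HPR, Hsd11b1 differed from diet by 1.42, -0.16 and -0.08 (adjusted p = 0.101). These organ values are given whether or not each passed within its organ.

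Of 5120 probe sets tested in all organs, 681 differed for Targretin, of which 178 were liver-dominant over all arrays and 195 on diet arrays, 19 for 9cRA and 0 for 4HPR, where 362 had an unadjusted p under 0.05 and chance would give 256. With array quality weights these counts were 1065, 389 and 291. The count for 9cRA moved with single arrays. It was 10, 7 and 2 without liver 9cRA arrays 1, 2 and 3, and 9, 1 and 6 without liver diet arrays 2, 3 and 4. It was 11, 8 and 82 without mammary 9cRA arrays 1, 2 and 4, 70, 8, 5 and 32 without mammary diet arrays 1, 2, 3 and 4, and 81 without lung diet array 2. The count for 4HPR was 89 without lung diet array 2, 1 without liver 4HPR array 1, liver 4HPR array 3, liver diet array 2 or mammary diet array 2, 3 without liver 4HPR array 4, and 2 without liver diet array 3 or 4.

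Calls for Targretin in liver overlapped with those in lung and in mammary gland. In liver and lung 28 probe sets were called in both, 26 in the same direction, where independent calls would give 14.7 (two-sided Fisher exact p = 6.5e-04). In liver and mammary gland there were 116, 76 in the same direction and 40 opposite, against 83.1 (exact p = 7.5e-05), and in lung and mammary gland 27, 26 in the same direction, against 17.9 (exact p = 0.0274). Both overlaps with lung were 0 without lung diet array 3 or lung diet array 4, and the last one also lost its call without other arrays, such as Targretin lung array 3 (exact p = 0.665) or diet lung array 2 (exact p = 0.858). The overlap of liver and mammary gland holds liver transcripts such as Ahsg, Apoa1 and Serpina1. With the liver-dominant probe sets left out, it was 74 against 55.0 (exact p = 0.00652), with 47 in the same direction. Organs may come from the same animals, which the labels do not say. The exact tests count probe sets as independent units, which they are not, since a gene can have several. Their p-values therefore do not measure the spread between arrays and can overstate the overlap. Among the genes shared by each pair of organs were Srebf1, Pex14 and Dnaja1, a heat shock cochaperone.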

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

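The tests of the 3 patterns weighed here were all chosen after the results were seen, while the counts of other groupings of the arrays were planned.

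Some arrays stood far from the others of their group of 4 in a quality measure. The log2 ratio of 3' to 5' signal on 4HPR liver array 4 was 1.18 for GAPDH, where the others had 0.219 to 0.290, and 1.57 for actin, where the others had 0.413 to 0.524. Its median signal of liver-restricted probe sets was 92.4% of the liver mean, where the others had 107.0 to 107.3%. On diet liver array 2 the 10th percentile of signal was 79.4, where the others had 31.2 to 37.4. On diet liver array 3 the actin ratio was 0.163, where the others had 0.395 to 0.442. Of 54 combinations of group and measure checked, 5 stood out, and chance flags about 1 in 20 groups, which would be 2.7.

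The change against diet differed between organs for 681 probe sets with Targretin and 19 with 9cRA. For Targretin the named genes were Acot1 (adjusted p = 2.1e-08), Serpina1 (1.5e-07), Acaa1b (2.0e-07), Cyp2b2 (2.4e-07), Atp1b1 (3.9e-07), Sult2a1 (4.8e-07), Dact2 (7.9e-07) and Cyp2c23 (2.8e-06). Of these, Serpina1, Sult2a1 and Cyp2c23 changed by -4.73, -5.86 and -3.83 in mammary gland and by -0.10, -0.17 and 0.00 in liver. For 9cRA they were Scd (8.1e-04), Cd74 and Crot (0.0137 each), Rpl26 and Stxbp5 (0.0179 each), Gstt2 (0.0310), and Prim1 and Asl (0.0370 each). Scd passed in every fit that left out 1 array, whereas each of the other 9cRA genes named here lost its call without liver diet array 3 (adjusted p between 0.0524 and 0.0578) and in further such fits, up to 0.0850 for Asl without mammary diet array 3.

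Transcripts of liver were lower on Targretin mammary arrays than on all 11 other mammary arrays. A scaling or background difference is argued against, since probe sets that are not liver-dominant had a median difference of 0.129 while the liver-restricted probe sets that were tested had -2.09. RNA of liver in the samples, as from shared handling of tissues, may account for it and stays open: 175 of 190 liver-restricted probe sets had an excess over the Targretin arrays, with a median of 3.20% of the liver signal, and 73.2% of the 190 lay within 3 times of that median, just under the share of 75% named as the mark of that explanation (72.6% of the 175 that are liver-dominant on the diet arrays). Lowering of these transcripts by Targretin stays open too and cannot be told apart from it, since all 11 arrays without Targretin lay above every Targretin array, so that agent and content of liver transcripts coincide. In lung, 2 untreated arrays, at 0.494 and 0.609%, were as low as the Targretin arrays, so a low level there did not need Targretin. Across the liver-restricted probe sets, the excess in signal in mammary gland rose with liver signal (Spearman 0.780). RNA of liver would give this, but the value does not forbid lowering by Targretin.

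Diet lung array 2 had a Cyp26b1 signal of 3280, within the 3075 to 6683 of the 4HPR lungs and apart from the 329 and 406 of the other diet lungs. RNA from the liver of a treated rat is argued against as the source of this Cyp26b1 signal. The highest Cyp26b1 signal in liver, taken at that array's liver share, would give 28.4. Whether the array holds such RNA was not tested and stays open. Cyp2c22, which rose with each agent in liver, was 2326.5 on this array and 121.2 and 402 on the other diet lungs. The 4HPR lungs had 951.5 to 6523.2 for Cyp2c22. A wrong label of this array is consistent with its mean Spearman correlation across genes, which was higher with the 4HPR lungs than with the other diet lungs by 0.0148 (0.945 against 0.930). The other diet lungs correlated at 0.973 with each other and at 0.940 with the 4HPR lungs. A difference between untreated animals was not tested and stays open, and the array was kept in its labelled group.

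Clock genes were lower in Targretin livers. High values in the shared diet arrays are argued against for Dbp, which was lower with Targretin also against 9cRA (-1.73, adjusted p = 0.0019) and 4HPR (-2.30, adjusted p = 1.2e-04). They stay open for Per2, Nr1d2 and Bhlhe41, which did not pass against either agent. The median of the smaller difference was -0.19, with -0.02 for Per2. Bhlhe41 differed by -1.12 from 9cRA and by -1.33 from 4HPR (limma adjusted p = 0.16 and 0.067). Another time of collection for the Targretin rats could lower them in every organ and stays open: the median change of the 4 clock genes called in liver was -1.96 in liver, -0.88 in lung and -0.36 in mammary gland, but the mean over all 8 was -1.02, -0.23 and 0.17, and Dbp differed by 0.03 in lung and 0.37 in mammary gland. An effect of Targretin itself stays open as well, as no collection times are given.

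Other groupings of the arrays into groups of the same sizes were counted for each comparison. In liver, chance is argued against for each, at a share of groupings under 0.05 that was not adjusted over the comparisons. In each, 1 of 35 groupings, the real one, gave as many calls. The counts were 678 for Targretin against a highest other of 17, 314 against 2 for 9cRA and 169 against 4 for 4HPR. Between agents in liver the values were 348 against 86 for Targretin and 9cRA, 479 against 192 for Targretin and 4HPR and 10 against 1 for 9cRA and 4HPR. In lung, the 10 groupings for Targretin are too few for a share under 0.05 (142, highest other 0). With 0 calls for 9cRA and 4HPR, all 35 groupings gave as many, with highest others of 0 and 65. The 65 came from 4HPR arrays 2, 3 and 4 with diet array 2 against the rest, which points to a structure of the samples. Chance is argued against in the same way for Targretin against 4HPR in lung (1 of 35, with 86 calls and 5 as the highest other). It is not for Targretin against 9cRA (4 of 35, with 1 call and 4 as the highest other). Nor is it for 9cRA against 4HPR (35 of 35, with 0 calls and 5 as the highest other).

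In mammary gland, chance is argued against for Targretin (1 of 35, with 796 calls). A grouping of diet arrays 2, 3 and 4 against the rest gave 577, however. With 0 calls for 9cRA and 4HPR, 35 of 35 groupings gave as many, with highest others of 408 and 0; the 408 parted 9cRA arrays 1, 2 and 3 with diet array 1 from the rest, which points to a structure of the samples. Chance is argued against for Targretin against 9cRA (1 of 35, with 124 calls and 84 as the highest other). It is not for 9cRA against 4HPR (4 of 35, with 3 calls and 10 as the highest other). The 10 groupings for Targretin against 4HPR are too few for a share under 0.05 (256, highest other 0). For the organ differences, 100 groupings were drawn. As many calls came from 2 of them for Targretin, the real one included (681, highest other 951). That share is under 0.05, which argues against chance. It does not exclude chance, since the other grouping gave more calls than the real one. As many came from 8 for 9cRA (19, highest other 70) and from 100 for 4HPR (0, highest other 107), where chance cannot be excluded either.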

How the results depend on the processing

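Leaving out the liver-dominant probe sets and leaving out the arrays in doubt were chosen after seeing the data, and the other alternatives were planned. Of 496 values of named genes that passed, 459 kept their side of the threshold under quantile normalization, 445 without a filter, 492 with a pseudocount 4 times larger, 398 with the block, 483 with array quality weights, 390 with only the 2 groups compared, 403 without the arrays in doubt, and 72 of 101 without the liver-dominant probe sets. Leaving out 1 array kept the call in 2684 cases and lost it in 822. None of these turned direction. Of 101 list results that passed, 88 were lost with an estimated correlation, 22 were lost and 3 turned under quantile normalization, and on leaving out 1 array 607 calls were kept and 116 lost. Signal over background limits genes of low signal: where the signal is near the pseudocount, log2 changes are compressed, and no detection calls were given. Except where an alternative tests fewer arrays or probe sets, the cause was not tested.

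With array quality weights the counts in liver were 483 for 9cRA, 443 for 4HPR and 22 for 9cRA against 4HPR. In lung they were 697 for Targretin, 964 for 9cRA, 398 for 4HPR, 44 for Targretin against 4HPR and 5 for 9cRA against 4HPR. In mammary gland they were 1308 for Targretin, 1108 for Targretin against 4HPR and 37 for 9cRA against 4HPR, and for the organ differences 1065, 389 and 291 for Targretin, 9cRA and 4HPR. With only the 2 groups compared, they were 292 for Targretin against 4HPR and 6 for 9cRA against 4HPR in liver. In lung this fit gave 0 for Targretin, 1 for 9cRA, 19 for Targretin against 9cRA, 39 for Targretin against 4HPR and 1 for 9cRA against 4HPR, and in mammary gland 458 for Targretin against 4HPR and 12 for 9cRA against 4HPR. The block for arrays of the same number, which the values do not pair, gave 6 for 9cRA against 4HPR in liver, 0, 2 and 25 for Targretin against diet, 9cRA and 4HPR in lung, 159 for Targretin and 1 for 9cRA against 4HPR in mammary gland, and 40 and 1 for the organ differences of 9cRA and 4HPR. Without a filter the counts were 1 for 9cRA and 2 for Targretin against 9cRA in lung, and 9 for the organ differences of 9cRA. Quantile normalization gave 2 for Targretin against 9cRA and 1 for 9cRA against 4HPR in lung, and 5 and 1 for the organ differences of 9cRA and 4HPR. The larger pseudocount gave 6 for 9cRA against 4HPR in mammary gland and 8 for the organ differences of 9cRA. Without the liver-dominant probe sets, Targretin against 9cRA and 4HPR gave 0 and 1 in lung and 0 and 0 in mammary gland, and 9cRA against 4HPR in mammary gland gave 6. With dominance judged on the diet arrays alone, these were 1, 1, 0, 0 and 6, Targretin against diet gave 198 in lung and 508 in mammary gland, and the organ differences gave 436, 14 and 0. Without the arrays in doubt the counts were 2 for 9cRA against 4HPR in lung, 409 for Targretin and 159 for Targretin against 4HPR in mammary gland, and 34 for the organ differences of 9cRA.

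Leaving out 1 array gave, from lowest to highest, in liver 420 to 587 for Targretin, 203 to 279 for 9cRA, 92 to 280 for 4HPR, 237 to 303 for Targretin against 9cRA, 280 to 491 for Targretin against 4HPR and 3 to 18 for 9cRA against 4HPR. In lung the ranges were 0 to 460, 0 to 38 and 0 to 80 against diet, and 0 to 5, 0 to 352 and 0 to 0 between agents in the same order. In mammary gland they were 338 to 1057, 0 to 147 and 0 to 0 against diet, and 96 to 140, 117 to 189 and 0 to 6 between agents. For organ differences they were 526 to 792, 1 to 82 and 0 to 89.

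Reversals were found for values near 0 that did not pass and for a list. Leaving out 1 array moved Rarb with 9cRA in liver from -0.10 to between -0.44 and 0.27, with 0.19 without 9cRA array 4 and 0.0445 without diet array 1. It moved Aldh1a1 with 4HPR in liver from -0.10 to between -0.29 and 0.0349, and Cyp26b1 for Targretin minus 4HPR in liver from -0.15 to between -0.44 and 0.115, with 0.00373 without 4HPR array 1. For 9cRA minus 4HPR in liver, Fasn went from -0.08 to between -0.17 and 0.00404, the latter without 4HPR array 4, the array in doubt there. Scd for the same agents went from 0.06 to -0.0234 under quantile normalization and -0.0206, -0.0896 and -0.0929 without 4HPR arrays 1 and 3 and 9cRA array 4. Cyp26b1 with 9cRA in lung, -0.30, was 0.49 with array quality weights and between -0.88 and 0.71 on leaving out 1 array. With 9cRA in mammary gland it was -0.20, and 0.0308 with array quality weights, with a range of -0.75 to 0.27 that held 0.14 and 0.0136 without 9cRA arrays 1 and 4 and 0.27 without diet array 1 or 4. Aldh1a1 with 4HPR in mammary gland, -0.01, was 0.0166 with the block, 0.14 with array quality weights, and between -0.12 and 0.17 on leaving out 1 array, with 0.0872 without diet array 1. The mean of the hepatocyte list in liver turned under quantile normalization, to -0.20 with 9cRA and to 0.0562 and 0.0568 for Targretin against 9cRA and 4HPR.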

Other observations

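The values given here were picked after the results were seen, and no test of a cause was run on them.

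Several further genes passed in Targretin livers, in lists that did not pass camera. The transporter gene Abcb11, which exports bile salts, rose by 1.15 ± 0.16, and Nr0b2, a repressor of bile acid synthesis, rose by 2.13 ± 0.22, while Nr1h4, the bile acid receptor gene, fell by 1.09 ± 0.21. In all, 3 of 17 bile acid genes rose, 3 fell and 11 did not pass, with 6 adjusted over the list alone (camera adjusted p = 0.97). Of 12 thyroid hormone responsive genes, 2 rose, 1 fell and 9 did not pass, with 4 adjusted over the list alone (camera adjusted p = 0.65), and Dio1, a deiodinase, fell by 1.08 ± 0.20. Of 16 sex-biased and growth hormone regulated genes, 1 rose, 3 fell and 12 did not pass, with 4 adjusted over the list alone (camera adjusted p = 0.48). Hao2 fell by 1.67 ± 0.26 and the growth hormone receptor gene Ghr by 1.11 ± 0.23. Histidine decarboxylase, Hdc, rose by 2.84 ± 0.47 and Flt1, an endothelial receptor of vascular growth factor, by 1.74 ± 0.32.

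Ghr also fell in Targretin mammary gland, by 2.06 ± 0.28. The bile salt exporter gene Abcb11 and the gluconeogenic enzyme Fbp1, both among the liver-restricted probe sets that were lower as a whole on Targretin mammary arrays, fell by 2.57 ± 0.37 and 3.67 ± 0.44. Of 15 bile acid genes in mammary gland, 4 fell, 0 rose and 11 did not pass, with 5 adjusted over the list alone and a mean of -0.72 (camera adjusted p = 0.0059, but adjusted p = 0.72 with an estimated correlation), and the 4 that fell, Abcb11, Baat, Slc10a1 and Slc27a2, all belong to the liver-restricted probe sets; the fall of Slc27a2 lost its call in some fits that left out 1 array.

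A probe set of Kctd13, an adaptor of ubiquitin ligases, varied widely within groups. On the Targretin livers its signal was 62907, 76676.4 and 7855.4, and on the Targretin lungs 53527.8, 119725 and 773.8, where diet livers had 917.1 to 1356.5 and diet lungs had 292.5 to 988.5. Its change in liver was 4.86 ± 0.71 (adjusted p = 2.0e-04), while the other probe sets of Kctd13 changed by 0.94 ± 0.67 (adjusted p = 0.439) and -0.25 ± 0.31 (adjusted p = 0.690). In Targretin mammary gland its signal was 326.8, 197.3 and 114.9.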
